A study of Mus musculus with 3 samples.

How the data were processed

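H3K27me3 was measured by ChIP-seq in kidney of C57BL/6 mice with an antibody from Cell Signaling Technology, per the labels. Libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. Groups were taken from the treatment and antibody labels, which gave 1 ADA-treated ChIP library, 1 untreated ChIP library and 1 input. The input entered only through the authors' peak calling, and the headers name a separate input for each library while the labels list 1. How many mice each library pools is not given in the sources used here.

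Peaks were called by the authors with MACS 2.1.2 in broad mode, separately for each library against its own input and not on pooled samples, per the file headers. The caller's p threshold was 0.001 for both the peaks and the broad regions, paired-end fragments were used, duplicates in the alignment files were kept, and the local background was switched off, per the file headers. The headers give 20602041 ChIP and 22100010 input fragments of 293 bp on average for the ADA-treated library, and 18849785 ChIP and 23891586 input fragments of 321 bp for the untreated library. The aligner is not given in the sources used here. The submitters' processing notes name CASAVA 1.4 and the build mm9.

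The deposited signal is the fragment pileup of a peak, averaged over its broad region. The deposited fold is the pileup plus 1 over the background plus 1, and within each list this background was one constant, 3.24 fragments in both, as the values and the switched-off local background show. A peak therefore records fragment density against one genome-wide level, and copy number, repeats and open chromatin are not corrected for by the input. The deposited −log10 p and −log10 q values are those of the caller. The file headers say that q was not calculated, although the column holds values, which are used as deposited. The smallest pileup listed was 10 in both lists, so a gene without a peak is below this threshold and not shown to lack the mark.

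The build was checked against the gene positions of the GRCm38.p6 gene table. Of the peak midpoints, 45.0% in the ADA-treated list and 43.7% in the untreated list lay within 1 kb of a gene end. The shares were 8.39% and 7.74% when the gene positions were shifted by -10 kb, and 8.58% and 7.94% when they were shifted by 10 kb. Unplaced sequences in the lists also carry GRCm38 names. Coordinates are therefore given as GRCm38, as the files hold them, 1-based, and the build in the processing notes was not used.

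Overlap of peaks was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and checked against bedtools 2.31.1, with a minimum overlap of 1 bp. The untreated peaks were placed at random within their chromosomes 1000 times for the random overlap (20 times under the other overlap rules). A gene counted as marked when a peak lay within 2 kb of either annotated end, over 21883 protein-coding genes. The peak of a marked gene can therefore lie outside the gene. The planned rule used transcription start sites, but the gene table carries neither strand nor transcripts, so both gene ends were used and exons, introns and UTRs are not distinguished. Adjacent genes can share 1 peak, which is stated where genes named in the text share one. The intervals and random lists treat genes as independent and do not allow for shared peaks. Each of 12 gene lists fixed before the data were examined was set against 10000 random gene lists of the same size within a library. The percentile describes that library and not the treatment. All list members matched the gene table. Gene families were chosen after the lists had been examined.

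Named genes followed a rule fixed before the data were examined. From each list came up to 4 genes per class (both libraries, ADA-treated alone, untreated alone) with the smallest caller p, then the largest fold. Outside the lists came 10 genes per class and 5 peaks per class. Nlrp3, Txnip, Egr1 and the PRC2 subunits were named whether or not they had a peak, and genes with Gm or Rik names were counted and not named. A few genes that the rule selects are not reported here.

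Shares carry exact binomial intervals at 95%. With 1 library per group no test between groups was run and no p-value is given. The overlap and gene counting were tested on simulated data, where 4000 of 4000 planted overlaps and 200 of 200 genes given a peak were recovered. Alternatives tried were a −log10 p of at least 10, a q of at most 5%, a fold of at least 10, lists of equal length, autosomes only, merging peaks within 1 kb, overlap of at least 50% of the shorter or of both peaks, shifting the peaks of a chromosome together, and gene windows of 5 kb, 0 bp or the whole gene with 2 kb on both sides. A set without mitochondrial and unplaced sequences and without peaks of a pileup of 40 or more was added after seeing the data. Figures were drawn with matplotlib 3.10.9.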

Results

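The mark H3K27me3, which the Polycomb complex PRC2 places at repressed genes, was mapped by ChIP-seq in whole kidney of C57BL/6 mice. The 3 samples were 1 H3K27me3 library from ADA-treated mice, 1 from untreated mice and 1 input. The file headers name a separate input of different size for each ChIP library, and which of them the labelled input is was not settled here. ADA is written as the labels give it. The series title also names mice lacking SAHH in podocytes, the filtering cells of the glomerulus, and that group was not analysed here. The ADA-treated library held 20602041 ChIP fragments and the untreated library 18849785, a ratio of 1.09. The deposited values were 2 lists of broad peaks, each called from 1 library, so no test between the groups was possible and no difference below has a replicate check. Percentages carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

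The comparison asks how H3K27me3 in the kidney differed between ADA-treated and untreated mice. Peaks of the ADA-treated library lay within 2 kb of an end of 10161 of 21883 protein-coding genes (46.4%, interval 45.8 to 47.1%), against 4979 genes (22.8%, 22.2 to 23.3%) for the untreated library. Both lists marked 4504 genes, the ADA-treated list alone marked 5657 (25.9% of all genes), and the untreated list alone marked 475 (2.17%). Genes marked in the ADA-treated list alone included Apoe, a lipid transport protein, Flt1 and Kdr, which encode VEGF receptors, and Suz12 and Eed, core subunits of PRC2. These are examples, and their functions are not shown to be particular to this library. Against random lists, the difference between the libraries in members marked ranked at percentiles 73.9 (endothelial and mesangial genes), 71.1 (PRC2 subunits and demethylases) and 72.0 (housekeeping genes). Genes marked in the untreated list alone included Terf2, a telomere-binding protein, Grm5, a glutamate receptor, and Pax5, a B-cell transcription factor.

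The genes marked in both lists were mostly marked at the same place. The strongest peaks of the 2 libraries overlapped at 3789 of these 4504 genes (84.1%, 83.0 to 85.2%) and lay apart at 715. Of the genes with an untreated peak, 90.5% (89.6 to 91.3%) also had an ADA-treated peak, while 44.3% (43.4 to 45.3%) of the genes with an ADA-treated peak had an untreated one. Lists of these sizes drawn independently would share 2312 genes. With a gene end required to lie inside the peak, the untreated library marked 2411 genes and the ADA-treated library 6777.

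The ADA-treated list held 17612 peaks covering 17.8 Mb, and the untreated list 8074 peaks covering 7.41 Mb, a ratio of 2.18 in number. Mean peak length was 1011 bp in the ADA-treated list and 918 bp in the untreated list. Fragment pileup, fold enrichment and p are the authors' own peak values and serve to describe, rank or filter the peaks of a list; counts above 1 pileup are set side by side because both lists have the same background of 3.24 fragments. The median fold enrichment was 2.97 in the ADA-treated list and 2.76 in the untreated list, so most regions of both lists lay close to the smallest listed pileup of 10 fragments. A deposited q of at most 5% was given to 10642 ADA-treated peaks and to 518 untreated peaks, a ratio of 20.5, but q is computed within each list and falls at a different strength in each. At a pileup of at least 12 in both lists, 7583 and 1131 peaks were left, a ratio of 6.70. With a fold enrichment of at least 10, the lists held 15 and 13 peaks, a ratio of 1.15, and these included the mitochondrial peaks.

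**Figure D1:**
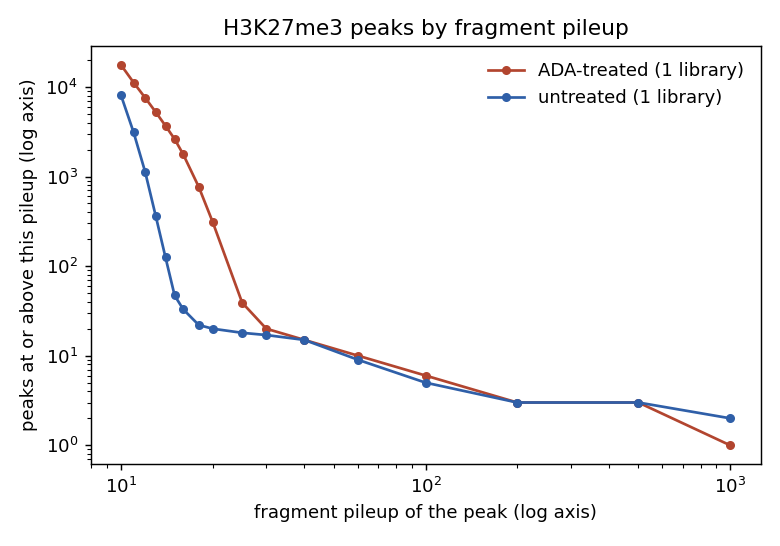
Number of H3K27me3 peaks (vertical axis, log scale) at or above each fragment pileup (horizontal axis, log scale, fragments) in the ADA-treated list and the untreated list, 1 library each. At a pileup of at least 15 the lists hold 2619 and 47 peaks, and from a pileup of 40 upwards, where both hold 15, the curves run close together.

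Regions found in both libraries lay at gene ends more often than regions found in 1 library. Of the 8074 untreated peaks, 4772 (59.1%, 58.0 to 60.2%) were overlapped by an ADA-treated peak, and of the 17612 ADA-treated peaks, 4756 (27%, 26.3 to 27.7%) were overlapped by an untreated one. Random placements of the untreated peaks gave 141 overlaps on average (range 101 to 176), so the observed number was 33.8 times the random one. The placements were uniform along each chromosome and did not keep the preference of both lists for gene ends. This ratio therefore also counts that shared preference and does not measure the agreement of the libraries alone. Of the shared ADA-treated peaks 76.9% (75.7 to 78.1%) lay within 2 kb of a gene end, against 48.1% (47.3 to 49.0%) of those without an untreated partner. For the untreated list these shares were 75.6% (74.3 to 76.8%) and 25.5% (24.0 to 27.1%), and 45.0% of the peaks found in this list alone lay further inside a gene. At random places 7.64% and 7.54% of the regions of the 2 lists fell near a gene end. The median fold enrichment of shared peaks was 3.44 (quartiles 3.01 and 3.99) in the ADA-treated list and 2.83 (2.70 and 3.01) in the untreated list. For peaks found in 1 list alone it was 2.87 and 2.70. Shared peaks were also longer, with medians of 1101 against 684 bp in the ADA-treated list and 773 against 628.5 bp in the untreated list. The shares at gene ends were not compared at equal length or strength. A reciprocal overlap of at least 50% lowered the shared fraction of untreated peaks to 29.6%.

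The strongest regions of both lists were mitochondrial DNA, a ribosomal RNA pseudogene and a few other short sites. The strongest nuclear peak, at chromosome 17, 39843005 to 39848841 (GRCm38), covered the annotated ribosomal RNA pseudogene Rn18s-rs5 with a fragment pileup of 1335 in the ADA-treated list and 677 in the untreated list. A peak inside Zc3h7a at chromosome 16, 11143898 to 11144313, had a pileup of 192 and 118, and a region at chromosome 2, 98664980 to 98667330, with no annotated gene under it, had 120 and 122. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, had the strongest peak near an end of a gene outside the fixed lists, with a pileup of 99.2 and 80.1. With the local background switched off, the input did not correct these sites for copy number or repeats. Their fragment density is therefore not shown to come from the mark.

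Other genes outside the lists with a peak in both libraries, ranked by the smaller of the 2 caller p, were Brox, Aida, Tomm40, Ybx2, Ubtd2, Bahd1, Jak2, Eif4e and Tmem267. Jak2, a cytokine receptor kinase, had a fold enrichment of 6.63 in the ADA-treated list and 3.26 in the untreated list, and Eif4e, the cap-binding translation factor, had 6.65 and 2.73. The untreated fold enrichments of Eif4e and of Ubtd2 (2.66) lay below that list's median of 2.76. The Tomm40 peaks lay at opposite ends of the gene in the 2 libraries, and those of Aida, which shares its untreated peak with Brox, did not overlap. The strongest region of the ADA-treated list without an untreated partner spanned Apoe and the adjacent end of Tomm40 (chromosome 7, 19696020 to 19703559), with a fold enrichment of 8.60. It was followed among named genes by Cmip, Tulp4, Scube3, Cobll1, Mier3, Gramd4, Sfpq, and Anxa9 with Cers2, which share 1 peak, at fold enrichments of 5.64 to 6.17. The Scube3 peak overlapped the neighbouring gene Zfp523. The strongest region of the untreated list without an ADA-treated partner lay inside Tmem267 (chromosome 13, 119492040 to 119492456), with a fold enrichment of 3.78. Of the genes marked in the untreated list alone, outside the fixed lists, Terf2 ranked first with 3.74, followed by Grm5, Gnal, Cep76 with Psmg2 under 1 peak, Cyp2s1, Adcy1, Slc9a8, Slc46a3 and Ankrd65, at 3.32 to 3.66.

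Developmental regulators known as PRC2 targets, the longest of the fixed lists, were marked far more often than genes overall in both libraries. A peak lay within 2 kb of an end of 64 of 82 of these genes (78.0%, 67.5 to 86.4%) in the ADA-treated library and of 47 (57.3%, 45.9 to 68.2%) in the untreated library. Both counts lay at percentile 100 of 10000 random lists of the same size within the library. Housekeeping genes, not expected to carry the mark, were also marked often, in 75% (50.9 to 91.3%) and 45% (23.1 to 68.5%), at percentiles 99.3 and 98.5. These intervals overlap those of the regulators, so the 2 lists were not clearly separated. Random lists also do not keep together neighbouring genes that share a peak, such as Hox genes. In both libraries peaks lay at Otx1, Neurod2, Nkx6-1 and Sox17, transcription factors of brain, neuronal, pancreatic and endodermal development, with ADA-treated fold enrichments of 3.99 to 4.68 and untreated ones of 2.63 to 3.16. Hoxc13, Lhx2, and Hoxd11 with Hoxd12 under 1 peak, which also lies within reach of Hoxd10, were marked in the ADA-treated list alone, at fold enrichments of 3.99 to 4.28. Pax5, Wnt1, Hoxa2 and Pax6 were marked in the untreated list alone, at 2.59 to 3.10. With a gene end required inside the peak, the housekeeping list stood at percentiles 90.2 and 96.1. The regulator counts then fell to 25 and 9, at percentiles 46.4 and 51.1, so their high rank rested on peaks beside the gene ends. Stricter calls also ended it in the untreated library: at a q of at most 5% the untreated count was 0 of 82 (percentile 8.7, with 465 genes marked overall) and the ADA-treated count 50 (percentile 100). At a −log10 p of at least 10 the ADA-treated count was 0 (percentile 9.5, with 440 genes marked).

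**Figure D2:**
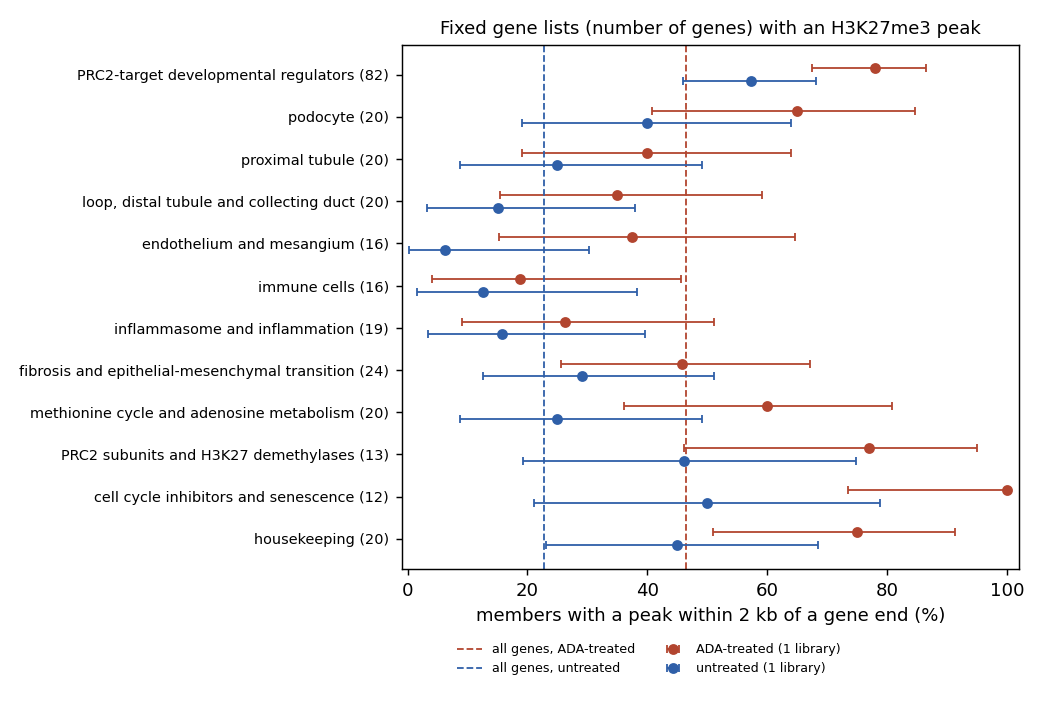
Share of the members of each fixed gene list (vertical axis, number of genes in parentheses) with an H3K27me3 peak within 2 kb of a gene end (horizontal axis, %), for the ADA-treated and the untreated library, 1 library each. Points are shares, bars are exact 95% intervals for counting error, and dashed lines mark all genes (46.4% and 22.8%). In the 12 lists the ADA-treated share is the higher one, as it is over all genes.

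Genes of PRC2 itself ranked high in the ADA-treated library, and in the untreated library by weak peaks only. Of 13 genes for PRC2 subunits and H3K27 demethylases, 10 (76.9%, 46.2 to 95%) had an ADA-treated peak and 6 (46.2%, 19.2 to 74.9%) an untreated one, at percentiles 98.5 and 96.5 of random lists. Jarid2, a PRC2 cofactor, had the strongest of these peaks in the ADA-treated list (chromosome 13, 44729817 to 44731294), with a fold enrichment of 5.67, and one of 2.81 in the untreated list. Ezh2, the methyltransferase that writes H3K27me3, had 4.13 and 3.12, the histone-binding subunit Rbbp4 4.11 and 2.93, Phf1 4.42 and 2.80, Aebp2 3.997 and 2.96, and the demethylase Kdm6b 2.94 and 2.97. The Kdm6b peaks of the 2 libraries lay at different places. The Phf1 peaks lay outside the gene, 1307 bp (ADA-treated) and 1292 bp (untreated) from an end of it. Suz12, Ezh1, Eed and Rbbp7 had a peak in the ADA-treated list alone, at fold enrichments of 4.21, 3.91, 3.41 and 2.65. Mtf2, Phf19 and Kdm6a had no peak in either list. The untreated rank was lost with a gene end required inside the peak (2 of 13, percentile 70.1) and at a q of at most 5% (0 of 13, percentile 38), and the housekeeping list, not expected to carry the mark, ranked at 99.3 and 98.5 in the 2 libraries.

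Cell cycle inhibitor and senescence genes were marked throughout in the ADA-treated library, in 12 of 12 genes (interval 73.5 to 100%, percentile 99.995), and in 6 of 12 (21.1 to 78.9%, percentile 97.8) in the untreated library. Cdkn1c, Igfbp3, Cdkn2a and Gadd45a had a peak in both lists, with ADA-treated fold enrichments of 4.03, 3.10, 3.35 and 3.08. Cdkn2a encodes the p16 and Arf tumour suppressors, and its peaks in the 2 libraries did not overlap. Rb1, Cdkn1b, Cdkn2b and Gadd45b were marked in the ADA-treated list alone, at 3.96, 3.02, 2.98 and 2.91. With the ADA-treated list reduced to its strongest 8074 peaks, 6 of 12 genes were marked in each library, at percentiles 89.8 and 97.96. The untreated count fell to 2 (percentile 73.8) with a gene end required inside the peak. At a q of at most 5% it fell to 1 (percentile 87.6), with 465 genes marked overall.

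Kidney cell type lists differed in how many members were marked. Podocyte genes were marked in 13 of 20 (65%, 40.8 to 84.6%, percentile 94.9) in the ADA-treated library and 8 of 20 (40%, 19.1 to 63.9%, percentile 95.7) in the untreated library. At a q of at most 5% none had an untreated peak, with 465 genes marked overall. Plce1, Cdkn1c, Vegfa and Inf2 had a peak in both, and Cd2ap, Kirrel, Wt1 and Podxl in the ADA-treated list alone, where Cd2ap, a slit diaphragm adaptor, had a fold enrichment of 4.16 and Wt1, the podocyte transcription factor, 3.04. Proximal tubule genes were marked in 8 of 20 and 5 of 20, at percentiles 27.9 and 60.8. Slc13a3 and Slc22a12 had a peak in both (those of Slc22a12 lay apart), Ass1, Pck1, Lrp2 and Slc34a1 in the ADA-treated list alone, and Slc22a8 and Hnf4a in the untreated list alone. Genes of the loop of Henle, distal tubule and collecting duct were marked in 7 of 20 and 3 of 20, at percentiles 15.7 and 21.3. The water channel gene Aqp2 had an ADA-treated peak with a fold enrichment of 2.68 and, elsewhere in the gene (chromosome 15, 99583727 to 99584205), an untreated one of 3.62. The peaks of Slc4a1 also lay at different places, and Aqp3, Pvalb, Slc26a4 and Slc12a3 were marked in the ADA-treated list alone. Endothelial and mesangial genes were marked in 6 of 16 and 1 of 16, at percentiles 24.2 and 5.39; Sox18 had a peak in both, and Flt1, Kdr, Des and Plvap in the ADA-treated list alone. Immune cell genes were marked in 3 of 16 and 2 of 16, at percentiles 1.17 and 17.2, with Cd4 in both, Cd68 and Cd8a in the ADA-treated list alone and Cd79b in the untreated list alone. The Cd4 peaks lay outside the gene, 518 bp (ADA-treated) and 638 bp (untreated) from an end. So did the Cd68 peak, at 1276 bp.

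Of 19 inflammasome and inflammation genes, 5 (26.3%, 9.15 to 51.2%) were marked in the ADA-treated library and 3 (15.8%, 3.38 to 39.6%) in the untreated library, at percentiles 4.28 and 25.3. Nlrp3, the sensor protein of the NLRP3 inflammasome, and Txnip, a thioredoxin-binding protein, had no peak within 2 kb of a gene end in either list. Egr1, an immediate early transcription factor, had a peak over the gene in both libraries, at chromosome 18, 34859882 to 34863146 with a fold enrichment of 3.54 in the ADA-treated list, and 34860280 to 34863179 with 2.82 in the untreated list. Rela, an NF-kB subunit, had 3.42 and 2.88, and Gsdmd, the pore-forming gasdermin D, 2.72 and 2.59. Icam1 and Nfkb1 were marked in the ADA-treated list alone, at 3.93 and 2.82.

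Fibrosis and epithelial-mesenchymal transition genes were marked in 11 of 24 and 7 of 24, at percentiles 48.5 and 77.4. Tgfbr1, a TGF-beta receptor, had a fold enrichment of 5.84 in the ADA-treated list and 3.09 in the untreated list, and the transcription factor Snai1 4.57 and 3.30. Tgfb1 and Twist1 also had peaks in both. Zeb1, Vim, and the adjacent collagen genes Col4a1 and Col4a2 under 1 peak were marked in the ADA-treated list alone, at 3.19 to 3.99, and Mmp9 in the untreated list alone, at 2.62. Methionine cycle and adenosine metabolism genes were marked in 12 of 20 (60%, 36.1 to 80.9%) and 5 of 20 (25%, 8.66 to 49.1%), at percentiles 88.1 and 60.8. Gamt, Ahcyl1 and Adk, the adenosine kinase gene, had peaks in both, although those of Gamt lay apart. Mtrr, Ahcyl2 and Nt5e were marked in the ADA-treated list alone, at 3.27 to 4.03, and Cbs and Mat2b in the untreated list alone.

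Housekeeping genes, chosen as a list not expected to carry the mark, were marked in 15 of 20 (75%, 50.9 to 91.3%, percentile 99.3) in the ADA-treated library and 9 of 20 (45%, 23.1 to 68.5%, percentile 98.5) in the untreated library. At a q of at most 5% 1 of 20 (percentile 79.3) had an untreated peak, with 465 genes marked overall. Actb, Eef2 and Tfrc had a peak in both, with ADA-treated fold enrichments of 4.10, 3.60 and 3.65 and untreated ones of 3.13, 3.38 and 3.14. Eef1a1, Ppia, Polr2a and Rps18 were marked in the ADA-treated list alone, at 3.54, 3.43, 2.87 and 2.72. Over the 281 genes of the 12 lists, 165 had an ADA-treated and 101 an untreated peak. The difference between the libraries in members marked was also set against that of random lists of the same size. It ranked from percentile 7.26 (immune cell genes) to 96.6 (cell cycle inhibitor and senescence genes). When the ADA-treated list was reduced to its strongest 8074 peaks, its count was higher in 6 of the 12 lists and equal in 3, and the order turned for developmental regulators (44 against 47), proximal tubule genes (3 against 5) and immune cell genes (0 against 2). Over all genes the reduced list still marked 7036 against 4979 in the untreated list.

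Genes on the X chromosome were rarely marked. Of 966 X-linked genes, 39 (4.04%, 2.89 to 5.48%) had an ADA-treated peak, among them Rbbp7, and 0 had an untreated peak (0 to 0.381%). On the 19 autosomes the share ran from 37.8% on chromosome 14 to 59.5% on chromosome 15 in the ADA-treated library, and from 16.4% on chromosome 13 to 31.3% on chromosome 15 in the untreated library. The X chromosome held 48 ADA-treated peaks and 1 untreated peak, and the Y chromosome held 0 in both lists. Chromosome 11, with 13.96 ADA-treated and 6.77 untreated peaks per Mb, was the most densely marked.

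**Figure D3:**
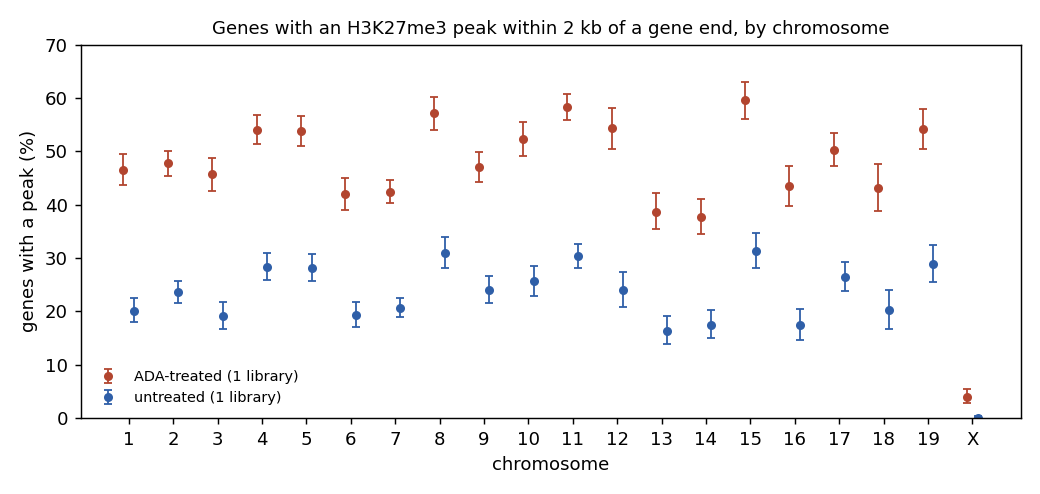
Share of protein-coding genes with an H3K27me3 peak within 2 kb of a gene end (vertical axis, %) by chromosome (horizontal axis) in the ADA-treated and the untreated library, 1 library each, with exact 95% intervals for counting error. The X chromosome, at 4.04% and 0%, lies below the 19 autosomes, whose lowest shares are 37.8% and 16.4%.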

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

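The tests of sequencing depth, of weak peaks, of ChIP efficiency, of the missing local background and of gene number on the X chromosome were chosen only after the result was seen. Sequences outside the nuclear chromosomes carried peaks in both lists, far above the background of 3.24 fragments. The mean pileup of the mitochondrial peaks was 811 in the ADA-treated list and 1503 in the untreated list, an estimated 0.168% and 0.331% of the ChIP fragments. The mean pileup over peaks on unplaced sequences was 33.9 in the ADA-treated list (18 peaks) and 36.3 in the untreated list (10 peaks).

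The ADA-treated list held 2.18 times as many peaks as the untreated list. Sequencing depth, taken as fragment coverage, is argued against, since the genome-wide backgrounds, which fragment number and length set, had a ratio of 0.999. Duplicates were kept, so a difference in the number of distinct fragments stays open. Weak peaks near the caller's threshold are argued against as well, since at a pileup of at least 12, with the same background in both lists, the ratio was 6.70 and not lower, although it was 1.15 among the 15 and 13 peaks with a fold of at least 10. A difference in ChIP efficiency between the 2 libraries could raise peaks of every function alike. With both lists at 8074 peaks, the ADA-treated count was the higher one in 6 of the 12 gene lists, equal in 3 and lower in 3. Over all genes the ADA-treated list then still marked 7036 against 4979, so an even split is not the value set by equal lists. With 1 library per group, a difference in ChIP efficiency cannot be told apart from an effect of the treatment, which stays open and untested.

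Housekeeping genes, which were not expected to carry the mark, ranked at percentile 99.3 of random lists in the ADA-treated library. If the 2 kb windows only reached into neighbouring promoters, the rank would fall once a gene end had to lie inside the peak. It was then 90.2, with 9 of 20 genes against 31.0% of all genes, and in the untreated library 96.1, with 5 of 20 against 11%. The ADA-treated rank lay between the limits set in advance, and none was set for the untreated library. The counts are small, so this explanation stays open in both libraries. Calling without a local background could admit regions that yield many fragments whatever their histones, and mitochondrial DNA, which carries none, was called in both lists, with a lowest fold of 172. That value does not reach the housekeeping genes themselves, so this explanation is open too. No biological explanation was tested, and GC content was not examined because no genome sequence was used here.

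X-linked genes with an ADA-treated peak made up 4.04%, below the lowest autosome at 37.8%, so a smaller number of genes on the X chromosome is argued against; chromosome 12, with the same 5.66 genes per Mb, had 54.3%. A single X copy per cell would lower the fragment density on this chromosome, and the labels used here give no sex. Under it, a share near that of autosomal genes whose strongest peak had at least 20 fragments, 1.41%, was set in advance, and a share over 2 times higher was to count against it. The observed share crossed that bound narrowly, with a lower limit of 2.89%. The bound was wrongly set, because a deposited pileup is a mean over the broad region and a peak with a mean below 20 can hold stretches above it, so 1.41% is a floor and a single X copy stays possible.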

How the results depend on the processing

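The set without mitochondrial, unplaced and very strong peaks was chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test, and no replicate could be left out. Counts of peaks, covered length, the ratio and the overlap shares stayed within their limits with autosomes alone and with merging within 1 kb, which joined no peaks, and, covered length aside, with that set. The observed over random overlap, not computed for that set, stayed above 1 in all other settings and moved to 36.6 on autosomes alone. In each set below, the cause was not tested beyond its own construction, which keeps fewer peaks, demands more overlap or narrows the window.

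With a −log10 p of at least 10, the lists held 451 ADA-treated and 21 untreated peaks (ratio 21.5) covering 0.710 and 0.111 Mb, of which 5.10% and 100% were overlapped, 3.49 times the random overlap; 440 and 5 genes, 2 and 0 list members were marked, and 17 of 129 named genes had the reported class. With a q of at most 5%, there were 10642 and 518 peaks (20.5) covering 11.8 and 0.626 Mb, of which 4.18% and 84.7% were overlapped, 33.2 times random; 465 genes and 5 list members were marked in the untreated library, and 71 named genes had the reported class. With a fold of at least 10, there were 15 and 13 peaks (1.15) covering 0.0741 and 0.0786 Mb, of which 80% and 92.3% were overlapped, 2.96 times random; 3 and 2 genes, 0 and 0 list members were marked, and 6 named genes had the reported class.

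With both lists at 8074 peaks (a ratio of 1 by construction), the ADA-treated peaks covered 9.42 Mb and marked 7036 genes and 108 list members. Of the peaks, 43.4% of ADA-treated and 43.7% of untreated ones were overlapped, and the overlap was 48.9 times random. ADA-treated minus untreated members were then -3 for developmental regulators, -2 for proximal tubule and -2 for immune cells. Overlap of at least 50% of the shorter peak gave shares of 24.5% and 53.5%, 43.9 times random. A reciprocal overlap of at least 50% gave 13.6% and 29.6%, 74.9 times random, and median folds of shared peaks of 3.59 and 2.84. With a gene end inside the peak, the untreated library marked 2411 genes, the list members marked were 90 and 32, and 67 named genes had the reported class. Over the 96 differences between the libraries per list and setting, 66 stayed above 0, 27 were at 0 and 3 were below. The smallest listed pileup of 10 fragments limits all counts, since 86.0% of untreated and 56.9% of ADA-treated peaks had fewer than 12.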

Other observations

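The gene families below were chosen after the peak lists had been examined, as were the Hox split and the comparison with gene ends inside both peaks; the other tests of the hypothesis were set before their results were seen. Hox, Fox and Sox genes, families of developmental transcription factors, were marked more often than most of the 13 families counted. A peak lay near 33 of 39 Hox genes (84.6%, 69.5 to 94.1%), 35 of 44 Fox genes (79.5%, 64.7 to 90.2%) and 17 of 19 Sox genes (89.5%, 66.9 to 98.7%) in the ADA-treated library. In the untreated library the counts were 14 Hox genes (35.9%, 21.2 to 52.8%), 30 Fox genes (68.2%, 52.4 to 81.4%) and 9 Sox genes (47.4%, 24.4 to 71.1%). Neighbouring Hox genes can share 1 peak, as Hoxd10, Hoxd11 and Hoxd12 did in the ADA-treated list. The intervals treat them as independent and are too narrow where peaks are shared. Families of chemosensory genes were almost free of peaks, with 2 of 1110 olfactory receptors in each library and 1 and 0 of 353 vomeronasal receptors. Cytochrome P450 genes, many of them enzymes of drug and steroid metabolism, were marked in 19 and 6 of 99, and histone genes in 18 and 8 of 97. Zfp genes, the largest family of transcription factors counted, lay below random lists, with 152 of 397 (38.3%, percentile 0.03) and 62 of 397 (15.6%, percentile 0.02), as did protocadherins (13 and 6 of 69), keratins (16 and 3 of 49) and defensins (3 and 1 of 72). Ribosomal protein genes were marked in 59 of 99 (59.6%, 49.3 to 69.3%, percentile 99.5) and 25 of 99 (percentile 72.5). Solute carriers were marked in 207 of 375 (55.2%, 50 to 60.3%, percentile 99.965) and 109 of 375 (29.1%, 24.5 to 33.9%, percentile 99.8). High ranks were therefore not limited to developmental families.

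Developmental regulators with an ADA-treated peak may also have an untreated peak more often than other genes marked as strongly in the ADA-treated list. Of the 64 regulators with an ADA-treated peak, 43 (67.2%, 54.3 to 78.4%) also had an untreated one, against 40.6% of random genes matched on the caller's p, at percentile 100; shorter lists had shares of 61.5% (podocyte), 60% (PRC2 subunits) and 60% (housekeeping), at percentiles 85.6, 61.5 and 93.8, and the differences from them were not tested. Wider peaks are argued against as the whole cause, since among genes matched on peak length (mean 50.8%) the list stood at percentile 99.7. Several separate peaks per window are argued against as the whole cause too, since 37 of the 78 ADA-treated peaks near these genes (47.4%, 36.0 to 59.1%) were overlapped by an untreated peak, at percentile 99.9 of peaks matched on strength (mean 31.9%), although the 37.1% of all peaks near other genes lies within that interval. These peaks were not matched on length, and the regulators had longer ADA-treated peaks (median 1254 bp against 857 bp over all genes with a peak). Wider peaks and several peaks per window acting together therefore stay open. The share was 9 of 19 for Hox genes and 34 of 45 for the other regulators (not tested). With a gene end required inside both peaks it was 6 of 25 (24%, 9.36 to 45.1%) against 29.5% of all genes. At a q of at most 5%, 50 of 82 regulators had an ADA-treated peak and 0 an untreated one, with 465 genes marked overall in the untreated library. The hypothesis therefore rests on weak peaks beside the gene ends and was not seen among the stricter calls.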
